A study of Mus musculus with 12 samples.

How the data were processed

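Livers of 12 adrenalectomized C57BL/6 mice were profiled, 3 males and 3 females after vehicle (phosphate-buffered saline) and 3 males and 3 females after dexamethasone, a synthetic glucocorticoid. Per the labels the animals were 11 weeks old, dexamethasone was given by intraperitoneal injection at 1 mg/kg, tissue was taken 6 h later, and females were in diestrus. Removal of the adrenal glands takes away the main source of the animal's own glucocorticoid. Total RNA (500 ng) was labelled with Cy3 and hybridized to 1-colour Agilent whole-genome mouse arrays, 1 animal per array. The labels name each array's slide and its position on the slide, and the slides were checked against the scanner files. Slide 1 held male vehicle 1, female vehicle 2, male dexamethasone 2 and female dexamethasone 2. Slide 2 held male vehicle 3, female vehicle 1 and female dexamethasone 1 and 3. Slide 3 held male vehicle 2, female vehicle 3 and male dexamethasone 1 and 3. All 3 male vehicle arrays sat at position 1. On each slide the male arrays sat at lower positions than the female arrays. Within a sex, vehicle arrays sat at lower positions than dexamethasone arrays of the same slide. How animals were assigned to treatments and arrays is not given in the sources used here.

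The deposited scanner files hold intensities per the file headers, quantified by the authors with Agilent Feature Extraction 9.5. The column used was the processed signal, an intensity that the authors' software had background-subtracted and detrended within each array, with surrogate values for spots near background. Each file held 45018 spots, 1639 of them controls, and the 43379 others represented 41174 probes. The deposited series values, also intensities per the file headers, equalled the processed signal for every spot. Signals were taken to log2, because the deposited values were on a linear scale per the file headers, and each array's 75th percentile over non-control spots was subtracted. The 75th percentile before scaling, a measure of signal depth, was 578 to 1251 over the 12 arrays, and 65.1 to 71.8% of probes were well above background by the scanner software's flag. There were 9, 1 and 1 saturated spots on female vehicle 2, male dexamethasone 2 and female dexamethasone 2.

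Spots flagged as outliers were left out, and the remaining spots of a probe were averaged. This dropped 57 probes that had only outlier spots on some array. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 28842 probes. Names came from the files and were brought to current symbols with a RefSeq gene table of assembly GRCm38.p6, used for names alone: 22951 probes were named by transcript accession, 6659 by symbol, 3109 by synonym, and 8455 kept the file's name. Where a gene had several probes, the probe with the brightest mean over the 12 arrays was used. This gave 19340 genes, 14727 of them with a usable symbol, and the others entered the tests but were not named. Coordinates are those of the array design file, on mm7, and no coordinate was converted.

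Genes were tested with limma 3.58.1 in R 4.3.3 (figures with matplotlib 3.10.9, files read with data.table version 1.17.8). A linear model with 4 group means was fitted to all 12 arrays, so that the comparisons shared 1 estimate of spread with 8 residual degrees of freedom, followed by empirical Bayes moderation. The 5 comparisons were dexamethasone against vehicle in males, the same in females, the female effect minus the male effect, and females against males under each treatment. P-values were adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05 and no fold threshold. The animal was the unit of replication. The effects in the 2 sexes shared no arrays, and neither did the 2 sex differences. Genes changed in the same direction in both sexes were counted as those past the threshold in both.

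Gene lists were tested with camera in limma at its preset correlation of 0.01, again with the correlation estimated from the arrays, and with fry. P-values were adjusted over the 30 lists within a comparison, with at least 3 members tested per list. A list's size was given as the median log2 fold change of its members, and its members were counted by the gene tests, adjusted over all genes and also over the list alone. The pathway lists, written from general knowledge, covered glucocorticoid receptor targets, gluconeogenesis, amino acid breakdown and urea cycle, insulin signalling and glycogen, fatty acid synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPAR alpha targets, bile acid synthesis and transport, xenobiotic metabolism, acute phase response, inflammatory cytokines and NF-kB, interferon response, growth hormone and IGF axis, circadian clock, male-biased liver genes, female-biased liver genes, Y-linked and X-inactivation genes, immediate early genes, heat shock and unfolded protein response, and cell cycle. The marker lists covered Kupffer cells and macrophages, neutrophils, T and NK cells, B cells, endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells, pancreatic acinar cells and adipocytes. Of 491 list symbols 489 were in the reference table.

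The genes named in the text followed a rule. For each comparison it took the 10 largest positive and 10 largest negative effects past the threshold (8 and 8 for the difference between the sexes) among genes with a usable symbol. For the comparisons of 2 groups it also asked that the 2 groups' arrays did not overlap, which chance gives in a share of 0.1 for 3 against 3 arrays. It added up to 4 members of each list past the threshold, by smallest adjusted p, and a fixed set of glucocorticoid-regulated and sex-specific genes. Members of the cholesterol list in the difference between the sexes and Hoxa2 were named outside this rule, after the values were seen.

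The alternative settings chosen before the data were examined were quantile normalization, median centring, cyclic loess, normexp background correction with offset 50, no filter on dim probes, probes above background on all 12 arrays, the mean of a gene's probes, slide as a block, replicate number as a block, fits on only the groups compared, an intensity trend with robust variance, array weights, a 2-fold threshold, an adjusted p below 0.01, and each of the 12 arrays left out in turn. Blocks were fitted as fixed terms beside the 4 group means. Leaving out an array of a group outside a comparison changes only the shared estimate of spread, not the fold change. List tests with a block or with an array left out used the preset correlation. Normexp with the local background capped near the top of each array's own distribution, a common floor under unfiltered signals, and leaving out the 2 arrays of lowest weight were added after the results were seen. Values within a slide are differences of group means among that slide's arrays. Those arrays also entered the fit, so a called gene's direction within a slide is largely fixed in advance and is no separate support.

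The fit was tested on simulated data in which 200 of 19340 genes were changed in each of 5 runs. The noise was normal, independent between genes, and for each gene of equal spread on all arrays. The real arrays differed in quality, with weights from 0.322 to 3.079, so these rates may not hold for them. For dexamethasone in females it recovered 9.6, 46.2 and 91.2% of changes of 1.5, 2 and 4-fold, with 4 false calls per run. For the difference between the sexes it recovered 0.4, 9.2 and 73.6%, with 3.2 false calls per run. For dexamethasone in males, where no change was simulated, 0 genes were called. Counts were also compared with those from the other 9 splits of 6 arrays into 3 and 3, and, for the difference between the sexes, with other assignments of sex within each treatment.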

Results

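Liver RNA was measured in 12 adrenalectomized C57BL/6 mice to compare how males and females respond to a glucocorticoid. The animals were 11 weeks old, and females were in diestrus. Each received vehicle or dexamethasone at 1 mg/kg, and livers were taken 6 h later. The 4 groups held 3 animals each, with 1 animal per single-colour Agilent array and 4 arrays on each of 3 slides. The upper-quartile signal of an array ranged from 578 to 1251 intensity units, and 65.1 to 71.8% of its probes were well above background. In all, 19340 genes were tested, 14727 of them with a usable gene symbol. Arrays of 1 group correlated at 0.984 to 0.994, and arrays of different groups at 0.954 to 0.986. The first principal component (41.5% of the variance) put all 6 dexamethasone arrays on 1 side and all 6 vehicle arrays on the other. The second (22.9%) separated the 6 male from the 6 female arrays. Effects below are log2 fold changes ± standard error from limma, with n = 3 arrays in each group, and p-values were adjusted over all genes. Where a gene was not well above background on any array of a group, only a lower bound is given, written as "at least". The groups, main tests, gene lists and naming rule were set before the data were examined, and so were all alternative settings but 3.

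The first question was what dexamethasone does in the male liver. Fam107a, which encodes an actin-associated protein, rose from below background at least 766-fold in males (adjusted p = 1.4e-05, n = 3 per group). Sult1e1, which encodes an estrogen sulfotransferase, rose by 7.96 ± 0.54 (adjusted p = 3.55e-05). Cdkn1a, which encodes a cyclin-dependent kinase inhibitor, rose by 6.92 ± 0.43 (adjusted p = 2.06e-05). Tg, which encodes thyroglobulin, rose from below background at least 77.8-fold (adjusted p = 5.11e-08). Gad2 and Atp6v0a4 rose at least 26.7-fold and at least 28.1-fold, and Gadd45b rose by 5.73 ± 0.77 (adjusted p = 0.000881). Acot3, an acyl-CoA thioesterase gene, had the largest loss among genes chosen by the naming rule, −5.24 ± 0.80 (adjusted p = 0.00163), and was above background on 1 of 3 dexamethasone arrays. The chemokine gene Cxcl10 fell by 5.06 ± 0.51 (adjusted p = 0.000234), and Ccl2 fell by 3.56 ± 0.40 (adjusted p = 0.000376). Slides 1 and 3 each held both male groups. Within them Sult1e1 differed by 9.66 and 7.23 and Cdkn1a by 6.43 and 6.58, and with slide as a block their adjusted p were 0.000434 and 0.000326. In the mm7 coordinates of the array design, the probes lie at chromosome 14, 6106017 to 6106076 for Fam107a, chromosome 5, 87512926 to 87512985 for Sult1e1, and chromosome 17, 27293819 to 27293878 for Cdkn1a. Exon and untranslated-region annotation of that build was not used here.

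Among 23 glucocorticoid receptor targets tested in males, 17 rose, 0 fell and 6 did not pass, and 20 rose when adjusted over the list alone. Fkbp5, a receptor co-chaperone gene and a standard glucocorticoid target, rose by 4.45 ± 0.43 (adjusted p = 0.000184), and the phosphatase gene Dusp1 by 3.15 ± 0.54 (adjusted p = 0.00288). Tat, which encodes tyrosine aminotransferase, rose by 1.91 ± 0.26 (adjusted p = 0.000882). Tsc22d3 rose by 1.54 ± 0.36 (adjusted p = 0.0131, but 0.0508 without male dexamethasone array 2). The list shifted higher (median 1.73, adjusted p = 8.02e-11, slide-block adjusted p = 1.98e-11, within slides 2.50 and 1.34). That shift had adjusted p = 0.238 with an estimated correlation. Per1 (1.28 ± 0.42, adjusted p = 0.0515; 0.0256 with slide as a block, 0.00889 without female vehicle array 1 and 0.044 without female vehicle array 2), Igfbp1 (2.40 ± 0.97, adjusted p = 0.101; 0.00556 without female dexamethasone array 3) and Pck1 (0.33 ± 0.15, adjusted p = 0.148) did not pass. The glucocorticoid receptor gene Nr3c1 (−0.25 ± 0.21, adjusted p = 0.433) and Hsd11b1 (0.02 ± 0.12, adjusted p = 0.939) did not pass either. Leaving out a female array changed only the shared spread, not these effects in males.

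Some genes of nitrogen and glucose metabolism also rose in males. Of 19 genes of amino acid breakdown and the urea cycle, 9 rose, 0 fell and 10 did not pass, with 9 rising when adjusted over the list alone. Aass, for lysine breakdown, rose by 2.34 ± 0.22 (adjusted p = 0.000177) and Sdsl by 2.31 ± 0.19 (adjusted p = 9.34e-05). The list's median was 0.47 (adjusted p = 0.000206, slide-block adjusted p = 0.000317, within slides 0.68 and 0.45), and adjusted p = 0.533 with an estimated correlation. It was 0.23 with quantile normalization and 0.26 without male vehicle array 1, and normexp ended the call (0.28, adjusted p = 0.0659). Of 14 gluconeogenesis genes 7 rose, 0 fell and 7 did not pass, and 7 rose when adjusted over the list alone. Gpt2 rose by 1.64 ± 0.21 (adjusted p = 0.00065) and the pyruvate carboxylase gene Pcx by 0.76 ± 0.12 (adjusted p = 0.00183), while the glucose-6-phosphatase gene G6pc was at −0.40 ± 0.58 (adjusted p = 0.684). The gluconeogenesis median was 0.52 (adjusted p = 0.00199, slide-block adjusted p = 0.000663, within slides 0.99 and 0.57), and adjusted p = 0.533 with an estimated correlation. It was 0.30 with quantile normalization, and normexp ended the call (0.28, adjusted p = 0.197). In the insulin signalling and glycogen list 3 rose, 3 fell and 8 did not pass. Its glycogen-targeting gene Ppp1r3c rose by 3.75 ± 0.41 (adjusted p = 0.000334), and its median of 0.44 was not called (adjusted p = 0.438).

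Some lipogenic genes fell in males. Srebf1, which encodes a transcription factor of lipid synthesis, fell by 3.06 ± 0.50 (adjusted p = 0.00224), Acly fell by 1.48 ± 0.29 (adjusted p = 0.00546) and Acaca fell by 1.42 ± 0.24 (adjusted p = 0.00263). Of 18 fatty acid synthesis genes 0 rose, 5 fell and 13 did not pass, while 1 rose and 7 fell when adjusted over the list alone. The list shifted lower (median −0.41, adjusted p = 0.0241, slide-block adjusted p = 0.0334, within slides −0.21 and −0.43), and adjusted p = 0.687 with an estimated correlation. Its call was lost with fry (adjusted p = 0.0555), and without male vehicle array 3 (adjusted p = 0.0666) or male dexamethasone array 3 (adjusted p = 0.196). Cholesterol synthesis and uptake genes were not called in males (2 higher, 3 lower, 17 not past, median −0.27, adjusted p = 0.264), although Sc5d fell by 0.89 ± 0.19 (adjusted p = 0.00892). Fatty acid oxidation genes were not called (1 higher, 4 lower, 16 not past, median −0.01, adjusted p = 0.869), and among them Ppara fell by 1.25 ± 0.22 (adjusted p = 0.00318) and Angptl4 rose by 1.78 ± 0.32 (adjusted p = 0.0037). Bile acid genes were not called (0 higher, 2 lower, 13 not past, median 0.01, adjusted p = 0.945), and their repressor gene Nr0b2 fell by 1.99 ± 0.28 (adjusted p = 0.00119). In the xenobiotic metabolism list, also not called (4 higher, 4 lower, 11 not past, median −0.04, adjusted p = 0.831), the cytochrome gene Cyp2b10 rose by 4.68 ± 0.26 (adjusted p = 1.06e-05).

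Interferon-induced genes fell widely in males. Ifit1 fell by 3.60 ± 0.33 (adjusted p = 0.000146), Ifit3 fell by 2.65 ± 0.20 (adjusted p = 7.1e-05) and Gbp2 fell by 1.84 ± 0.17 (adjusted p = 0.000179). Of 25 interferon genes 0 rose, 20 fell and 5 did not pass, and 21 fell when adjusted over the list alone. Their median was −1.45 (adjusted p = 5.47e-13, slide-block adjusted p = 6.67e-14, within slides −1.67 and −1.46), and adjusted p = 0.0587 with an estimated correlation. Of 25 inflammatory and NF-kB genes 3 rose, 10 fell and 12 did not pass, while 3 rose and 13 fell when adjusted over the list alone. Relb fell by 1.86 ± 0.24 (adjusted p = 0.00071), whereas the interleukin receptor gene Il1r1 rose by 2.91 ± 0.36 (adjusted p = 0.00065). That list's median was −0.96 (adjusted p = 0.00199, slide-block adjusted p = 0.0012, within slide 3 −1.06), and adjusted p = 0.533 with an estimated correlation. The acute phase list was not called (3 higher, 1 lower, 16 not past, median 0.07, adjusted p = 0.427).

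Cell cycle genes fell in males. The replication helicase genes Mcm2 (−1.70 ± 0.19, adjusted p = 0.000376) and Mcm5 (−1.34 ± 0.26, adjusted p = 0.00527) fell, and so did Tk1 (−1.27 ± 0.23, adjusted p = 0.00344). Rrm2, a subunit of ribonucleotide reductase, rose instead by 1.55 ± 0.37 (adjusted p = 0.0144; 0.0588 without male vehicle array 1 and 0.0541 without male dexamethasone array 2). Of 19 members 1 rose, 11 fell and 7 did not pass, while 1 rose and 15 fell when adjusted over the list alone. The median was −1.27 (adjusted p = 6.33e-05, slide-block adjusted p = 6.42e-05, within slides −1.26 and −1.62), and adjusted p = 0.533 with an estimated correlation. Clock genes split: Arntl rose by 3.28 ± 0.16 (adjusted p = 5.7e-06) and Clock by 1.59 ± 0.23 (adjusted p = 0.00128), whereas Dbp fell by 3.704 ± 0.26 (adjusted p = 4.38e-05) and Per3 fell by 2.19 ± 0.30 (adjusted p = 0.00105). With 3 higher, 6 lower and 8 not past, the clock list had no single direction (median −0.43, adjusted p = 0.493).

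Some markers of B cells and of T and NK cells fell in male liver, and these RNA levels do not count cells. Of 10 B cell markers 0 rose, 5 fell and 5 did not pass, with 5 falling when adjusted over the list alone. The B cell surface gene Ms4a1 fell by 3.02 ± 0.43 (adjusted p = 0.00113), and the median was −1.34 (adjusted p = 0.00329, slide-block adjusted p = 0.00372, within slides −1.28 and −1.42), and adjusted p = 0.555 with an estimated correlation. Normexp turned this median to 0.44 (adjusted p = 0.627), and with a capped local background it was −0.10 (adjusted p = 0.0594). Of 17 T and NK cell markers 0 rose, 6 fell and 11 did not pass, while 2 rose and 7 fell when adjusted over the list alone. Ccr7 fell at least 2.65-fold (adjusted p = 0.00512), and the granzyme gene Gzmb fell by 1.55 ± 0.31 (adjusted p = 0.00597). The median of −0.66 (adjusted p = 0.014, slide-block adjusted p = 0.0251, within slides −0.58 and −0.91) had adjusted p = 0.687 with an estimated correlation, turned to 0.40 after normexp background correction, and lost its call without male dexamethasone array 1 (adjusted p = 0.0548). The call was also lost with a capped local background (median −0.19, adjusted p = 0.183) with probes above background on all 12 arrays (0.0563) and with fry (0.0813). Normexp also turned Gzmb to 0.36 and Ccr7 to 0.56. Kupffer cell and macrophage markers had 1 higher, 2 lower and 10 not past (1 and 4 when adjusted over the list alone), and Cd163 rose by 1.51 ± 0.34 (adjusted p = 0.00965). Their median of −0.58 (adjusted p = 0.0496) had adjusted p = 0.736 with an estimated correlation. It was not called with slide as a block (adjusted p = 0.182), with the mean of a gene's probes (0.102), with replicate block (0.0502), with array weights (0.0703) or with fry (0.237), nor without male vehicle array 1 (0.184), female vehicle array 2 (0.0601), male dexamethasone array 3 (0.196) or female dexamethasone array 1 (0.0539).

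Smaller shifts in males were less stable. Among Y-linked and X-inactivation genes 3 rose, 0 fell and 5 did not pass (4 rose when adjusted over the list alone). Those that rose are carried on the X chromosome, among them Kdm5c (1.00 ± 0.13, adjusted p = 0.000884) and Eif2s3x (0.54 ± 0.12, adjusted p = 0.011). The list's median was 0.39 (adjusted p = 0.0239, slide-block adjusted p = 0.0251, within slides 0.46 and 0.35), and adjusted p = 0.238 with an estimated correlation. Normexp ended this call with and without a capped local background (adjusted p = 0.0594 and 0.265). Of 14 immediate early genes 2 rose, 0 fell and 12 did not pass (1 rose when adjusted over the list alone), and Jun rose by 1.85 ± 0.34 (adjusted p = 0.00402). Their median was 0.58 (adjusted p = 0.0305, slide-block adjusted p = 0.0142, within slides 0.18 and 0.90), and adjusted p = 0.687 with an estimated correlation. The call was lost without a filter on dim probes (0.0707), with a capped local background (0.0594), with fry (0.138), and without male vehicle array 2 (0.0656), male vehicle array 3 (0.0568) or male dexamethasone array 3 (0.128). Of 15 heat shock and unfolded protein response genes 3 rose, 0 fell and 12 did not pass (3 rose when adjusted over the list alone), and the asparagine synthetase gene Asns rose by 1.59 ± 0.30 (adjusted p = 0.00424). That median of 0.24 (adjusted p = 0.0496) had adjusted p = 0.533 with an estimated correlation and 0.112 with slide as a block. Besides these, 10 other settings ended this call (among them quantile normalization, 0.132, and normexp, 0.627). It was also lost without any 1 of male vehicle arrays 1 and 3, female vehicle array 2, male dexamethasone array 3 and female dexamethasone arrays 1 and 3 (highest adjusted p = 0.196). Lists not called in males were the growth hormone and IGF axis (median −0.22, adjusted p = 0.945), male-biased genes (0.27, 0.0769), female-biased genes (0.39, 0.244), and markers of neutrophils (−0.98, 0.244), endothelial cells (−0.23, 0.225), stellate cells and fibroblasts (−0.35, 0.214), cholangiocytes (−0.43, 0.438), erythroid cells (−0.04, 0.831), pancreatic acinar cells (0.05, 0.812) and adipocytes (0.02, 0.635). Single genes passed in some of them, such as Socs2 (2.62 ± 0.58, adjusted p = 0.00969) and Cyp2b13 (4.197 ± 0.39, adjusted p = 0.000165; 1 of its 2 probes had the other sign).

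By the limma test 4359 genes changed in males, 2020 higher and 2339 lower, and 1887 of them by at least 2-fold. All but 2 of the calls kept their direction within slide 1, and all did within slide 3, while over all genes 87.8% and 85.5% did. The same arrays made the calls, so this agreement was largely built in. With slide as a block 3187 genes passed, and without male vehicle array 1 only 2342 did. Normexp background correction left 899 calls and moved the median of all genes by 0.25. Its fitted mean background was extreme on male dexamethasone array 1 (−399) and female dexamethasone array 3 (−514.7), and with a capped local background 3594 genes passed. All 3 male vehicle arrays sat at the same slide position, below the male dexamethasone arrays of their slides, so position and treatment could not be told apart. The 10 ways to split these 6 arrays into 3 and 3 were too few for a test by chance (the real split gave 4359, the highest other 0).

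The second question was what dexamethasone does in the female liver. Fam107a rose from below background at least 477-fold in females (adjusted p = 5.05e-05, n = 3 per group). Sult1e1 rose by 8.27 ± 0.54 and Cdkn1a by 6.34 ± 0.43 (both adjusted p = 5.05e-05). Serpina5, a protease inhibitor gene, rose at least 80.7-fold (adjusted p = 5.05e-05), and Tff3, which encodes a trefoil peptide, by 5.42 ± 0.66 (adjusted p = 0.000926). Plin4, a lipid droplet coat gene, rose by 4.55 ± 0.30 (adjusted p = 5.05e-05). Acot3 fell by 4.73 ± 0.80 (adjusted p = 0.00489), Nfe2 fell by 4.21 ± 0.39 (adjusted p = 0.00027), and Zbp1, which encodes a nucleic acid sensor, fell by 3.59 ± 0.31 (adjusted p = 0.000182). Slides 1 and 2 each held both female groups. Within them Sult1e1 differed by 7.50 and 8.87 and Plin4 by 4.10 and 4.71, and with slide as a block both had adjusted p = 0.00069.

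Of 23 glucocorticoid receptor targets tested in females, 13 rose, 0 fell and 10 did not pass, and 18 rose when adjusted over the list alone. Fkbp5 rose by 3.86 ± 0.43 (adjusted p = 0.000595), Dusp1 by 2.72 ± 0.54 (adjusted p = 0.00954) and Tat by 1.64 ± 0.26 (adjusted p = 0.00317). Tsc22d3 rose by 1.76 ± 0.36 (adjusted p = 0.0115). The median was 1.502 (adjusted p = 4.22e-11, slide-block adjusted p = 1.34e-10, within slides 1.47 and 1.54), and adjusted p = 0.277 with an estimated correlation. It was 0.99 without female vehicle array 2 and female dexamethasone array 3 together. Per1 (1.24 ± 0.42, adjusted p = 0.0785; 0.00891 without female vehicle array 1), Sgk1 (0.78 ± 0.64, adjusted p = 0.473), Igfbp1 (2.11 ± 0.97, adjusted p = 0.182) and Pck1 (0.41 ± 0.15, adjusted p = 0.0971) did not pass. G6pc did not pass at 1.78 ± 0.58 (adjusted p = 0.0669), but passed without male dexamethasone array 2 (0.0453) or 3 (0.0185). Leaving out these male arrays changed only the shared spread, not the effect in females.

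Amino acid breakdown and the urea cycle had 11 genes higher, 0 lower and 8 not past in females, with 11 rising when adjusted over the list alone. Sdsl rose by 2.21 ± 0.19 (adjusted p = 0.000182) and Tdo2, for tryptophan breakdown, by 2.38 ± 0.27 (adjusted p = 0.000638). The median was 0.78 (adjusted p = 1.53e-06, slide-block adjusted p = 1.42e-05, within slides 0.36 and 0.94), and adjusted p = 0.426 with an estimated correlation. Gluconeogenesis had 6 higher, 0 lower and 8 not past, and 9 rose when adjusted over the list alone. Gpt2 rose by 1.78 ± 0.21 (adjusted p = 0.000744) and the transcription factor gene Foxo1 by 1.49 ± 0.21 (adjusted p = 0.00174). Its median was 0.72 (adjusted p = 8.79e-06, slide-block adjusted p = 0.000104, within slides 0.39 and 0.80), and adjusted p = 0.426 with an estimated correlation.

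Sterol genes fell in females. Mvd, a mevalonate pathway gene, fell by 3.33 ± 0.43 (adjusted p = 0.00117), and Insig1 fell by 1.86 ± 0.30 (adjusted p = 0.00348). Of 22 cholesterol synthesis and uptake genes 0 rose, 14 fell and 8 did not pass, while 1 rose and 18 fell when adjusted over the list alone. The median was −1.23 (adjusted p = 8.11e-10, slide-block adjusted p = 6.9e-09, within slides −1.72 and −0.71), and adjusted p = 0.426 with an estimated correlation. Of 18 fatty acid synthesis genes 0 rose, 5 fell and 13 did not pass, with 6 falling when adjusted over the list alone. Elovl6 fell by 1.80 ± 0.37 (adjusted p = 0.0115) and Fasn, fatty acid synthase, fell by 1.10 ± 0.20 (adjusted p = 0.0071). That median was −0.58 (adjusted p = 0.000653, slide-block adjusted p = 0.000738, within slides −0.47 and −0.48), and adjusted p = 0.501 with an estimated correlation.

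Interferon genes fell in females as well: 0 rose, 22 fell and 3 did not pass, and 22 fell when adjusted over the list alone. Ifit1 fell by 3.13 ± 0.33 (adjusted p = 0.00041), Ifit3 fell by 2.27 ± 0.20 (adjusted p = 0.000202) and the immunoproteasome gene Psmb9 fell by 1.52 ± 0.15 (adjusted p = 0.000328). The median was −1.44 (adjusted p = 2.98e-16, slide-block adjusted p = 1.71e-16, within slides −1.42 and −1.21), and the call held with an estimated correlation (adjusted p = 0.0294). Inflammatory genes had 3 higher, 8 lower and 14 not past (3 and 8 when adjusted over the list alone), with Ccl2 at −2.78 ± 0.40 (adjusted p = 0.00223) but Il6ra higher by 1.81 ± 0.26 (adjusted p = 0.00228). Their median was −0.70 (adjusted p = 0.00224, slide-block adjusted p = 0.0065, within slides −0.74 and −1.02), and adjusted p = 0.501 with an estimated correlation. Of 10 B cell markers 0 rose, 4 fell and 6 did not pass, with 7 falling when adjusted over the list alone. Ms4a1 fell by 2.33 ± 0.43 (adjusted p = 0.00692), and the B cell median was −1.39 (adjusted p = 0.000233, slide-block adjusted p = 0.000104, within slides −1.04 and −1.60), and adjusted p = 0.501 with an estimated correlation. Normexp turned it to 0.21 (adjusted p = 0.404), and with a capped local background it was −0.47 and stayed called. T and NK cell markers (median −0.34, adjusted p = 0.17) and Kupffer cell markers (−0.26, 0.289; 0.042 with slide as a block) were not called.

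Cell cycle genes in females had 1 higher, 5 lower and 13 not past, and the same 1 and 5 when adjusted over the list alone. Mcm5 fell by 2.02 ± 0.26 (adjusted p = 0.00128) and Mcm2 fell by 1.59 ± 0.19 (adjusted p = 0.000939), and Rrm2 rose by 2.99 ± 0.37 (adjusted p = 0.00108). The median was −0.74 (adjusted p = 0.000628, slide-block adjusted p = 0.000166, within slides −1.20 and −0.82), and adjusted p = 0.694 with an estimated correlation and 0.0891 with fry. Among clock genes Arntl rose by 4.17 ± 0.16 (adjusted p = 9.85e-07) and Clock by 1.82 ± 0.23 (adjusted p = 0.00111), while Dbp fell by 3.34 ± 0.26 (adjusted p = 0.000114) and Per3 fell by 2.46 ± 0.30 (adjusted p = 0.00102). With 5 higher, 5 lower and 7 not past, the clock list again had no single direction (median 0.20, adjusted p = 0.81). Cyp2b10 rose by 3.49 ± 0.26 (adjusted p = 9.29e-05) in a xenobiotic list that was not called (1 higher, 2 lower, 16 not past, median 0.05, adjusted p = 0.81).

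In females 2644 genes passed in limma, 1313 higher and 1331 lower, and 1149 of them changed by at least 2-fold. All but 1 of the calls kept their direction within slide 1 and all did within slide 2, while over all genes 80.5% and 84.9% did. Here too the agreement was largely built in, because the same arrays made the calls. With slide as a block 1779 passed, without female vehicle array 1, female vehicle array 3 or female dexamethasone array 2 the counts were 1504, 1742 and 1703, and fitted on the female arrays alone 1180. Normexp left 508 and moved the median of all genes by 0.21. Within slides 1 and 2 the female vehicle arrays sat at lower positions than the female dexamethasone arrays. Position and treatment could therefore not be told apart within a slide. The 10 splits were too few for a test by chance (the real split gave 2644, the highest other 2).

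The responses of the 2 sexes overlapped more than independent lists would. Arntl, Fkbp5, Sult1e1, Cdkn1a and Rrm2 rose in both sexes, and Dbp, Ifit1, Mcm2, Ms4a1 and Acly fell in both. In total 925 genes rose in both (137 expected for independent lists) and 1078 fell in both (161 expected). Over all 19340 genes the effects correlated at 0.797, and among the 2003 shared genes the median size was 1.07 in males and 0.95 in females. Of 2355 genes that passed in males alone 95.7% had the same sign in females, and of 640 that passed in females alone 93.1% had the same sign in males. Passing in 1 sex is therefore not evidence of a difference. The homeobox gene Hoxa2, picked after the values were seen, was the only gene that passed in opposite directions (males −0.64 ± 0.14, adjusted p = 0.00904, females 0.50 ± 0.14, adjusted p = 0.0397). Its difference of 1.14 ± 0.20 did not pass (adjusted p = 0.282). The 2003 shared genes became 1277 with slide as a block, 379 after normexp, 1327 without male vehicle array 1 and 1196 without female vehicle array 1. Males had more calls than females with equal numbers of arrays. They also did with any 1 male array left out, which leaves males with fewer arrays. The counts in males and females were 2342 and 2317 without male vehicle array 1, 3085 and 2177 without array 2, and 3186 and 2248 without array 3. Without male dexamethasone array 1 they were 3487 and 2329, without array 2 3104 and 2445, and without array 3 3361 and 2568. Without female vehicle array 1, which leaves females with fewer arrays, they were 4088 and 1504. A count is not a test of whether the response differs.

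**Figure D1:**
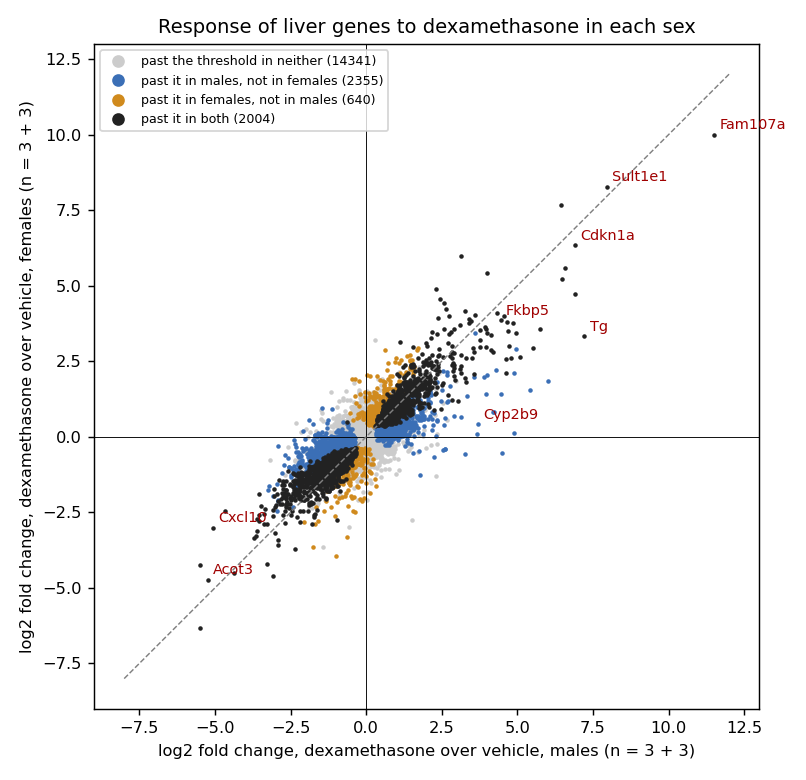
Effect of dexamethasone on each tested gene in males and in females, as log2 fold change. Each effect compares 3 dexamethasone with 3 vehicle arrays, and colour shows in which sex the gene passed.

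**Figure D2:**
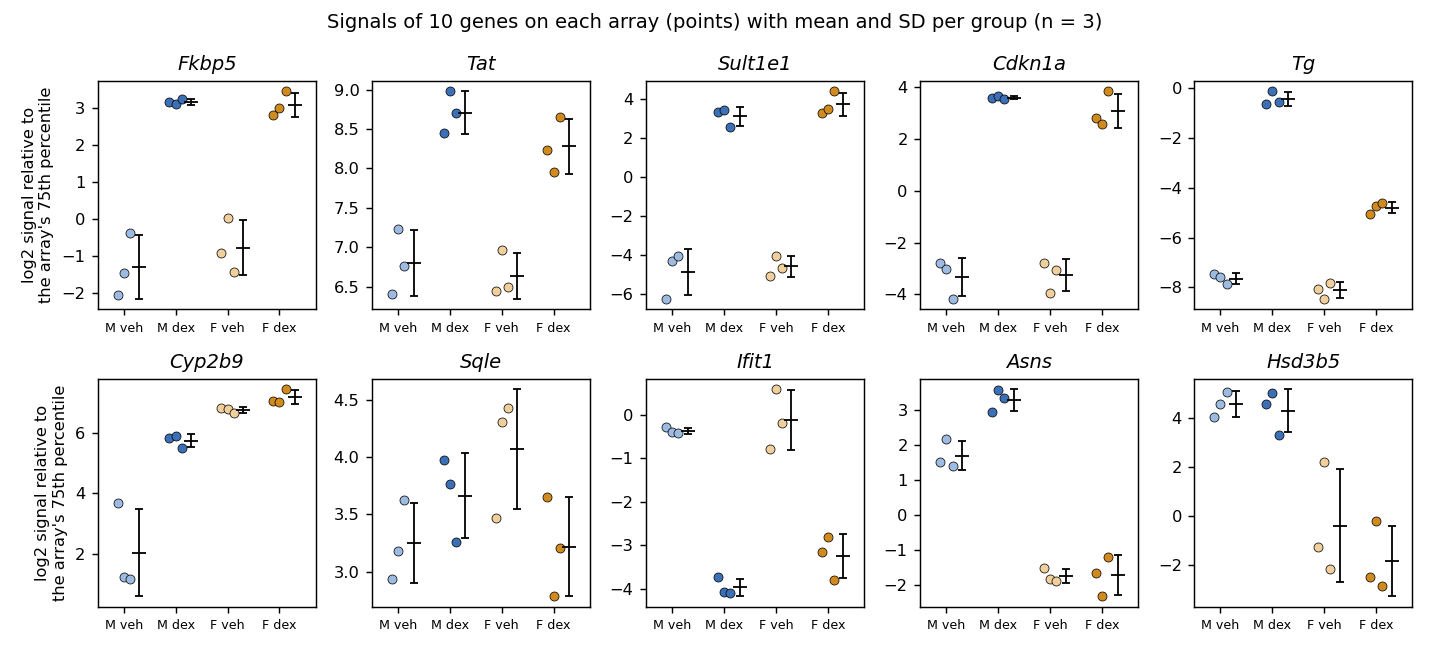
Signal of 10 genes on each of the 12 arrays, relative to the array's own upper quartile. Each point is 1 animal, with 3 animals per group.

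**Figure D3:**
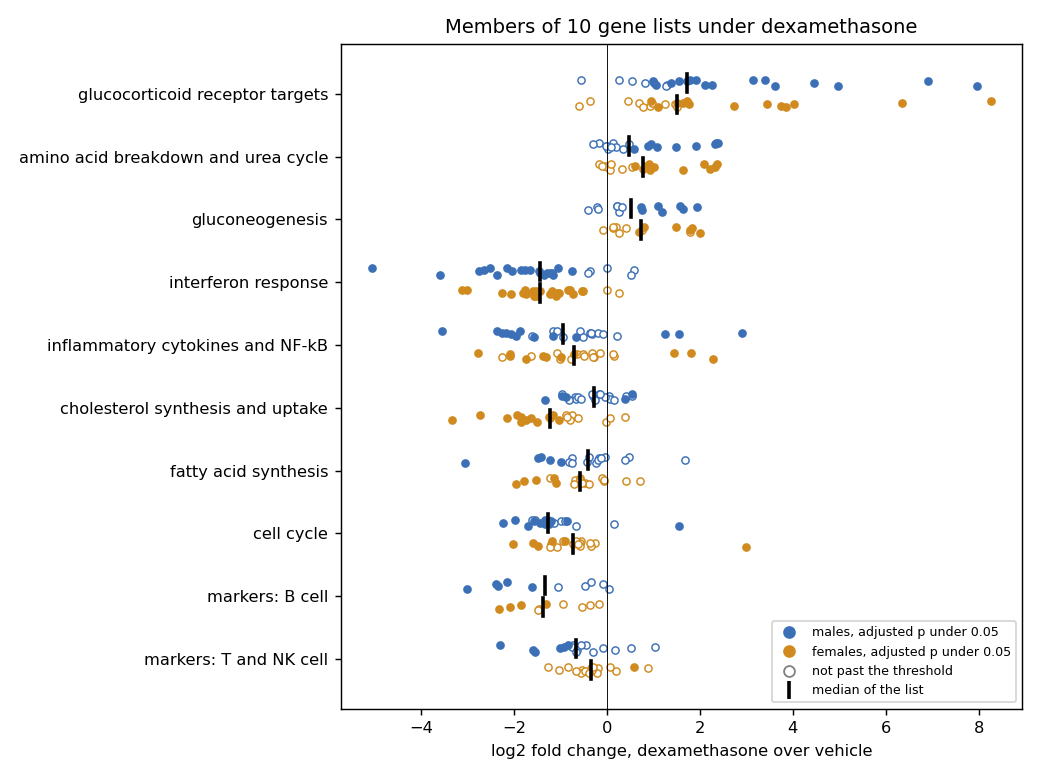
Effects of dexamethasone on the members of 10 gene lists in males and in females. Each point is 1 gene, measured on 3 arrays per group.

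The third question was whether the response differs between the sexes, tested as the female effect minus the male effect. Tg was the only gene that the fit called (adjusted p = 0.00112, n = 3 in each of 4 groups). It was above background on 0 of 6 vehicle arrays and on all 6 dexamethasone arrays. In females it rose from below background with adjusted p = 5.05e-05, and under dexamethasone its level in females was −4.36 ± 0.21 relative to males (adjusted p = 1.44e-06). Because neither vehicle group was above background, both effects are lower bounds, and neither the size nor the direction of their difference was measured. The probe lies at chromosome 15, 66934195 to 66934254 in mm7. The female-biased cytochrome gene Cyp2b9 rose in males by 3.69 ± 0.53 (adjusted p = 0.00123) and was at 0.42 ± 0.53 in females (adjusted p = 0.667). Its difference was −3.27 ± 0.75 (adjusted p = 0.475), but without male vehicle array 1 it was −4.10 and passed (adjusted p = 0.000245). Fkbp5 (−0.59 ± 0.60, adjusted p = 1), Tat (−0.27 ± 0.36, adjusted p = 1) and G6pc (2.18 ± 0.82, adjusted p = 0.853) did not pass this test.

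All 22 cholesterol synthesis and uptake genes had a lower effect in females than in males, although 0 of them passed over all genes. Adjusted over the list alone 4 were lower, among them Mvd (−2.70, adjusted p = 0.016) and Lss (−1.10, adjusted p = 0.0354). The list's median difference was −0.93 (adjusted p = 1.93e-15, slide-block adjusted p = 6.1e-12, within slide 1 −1.52), and adjusted p = 0.28 with an estimated correlation. Part of it lies in the vehicle groups, where the list's median was 0.606 higher in females. Slide position and the male vehicle group could not be told apart. Immediate early genes (median −0.70, adjusted p = 0.00725, slide-block 0.0021, within slide 1 only −0.02) and heat shock genes (−0.53, 0.00016, slide-block 0.0115, within slide 1 −0.34) also had lower effects in females. These had adjusted p = 0.809 and adjusted p = 0.194 with an estimated correlation, and the first was lost without female vehicle array 1 (median −0.30, adjusted p = 0.0941). Without a filter on dim probes neither was called (0.252 and 0.0876), nor were heat shock genes without both low-weight arrays (0.123). Y-linked and X-inactivation genes shifted lower (−0.24, adjusted p = 0.00133, slide-block 0.0115, within slide 1 −0.27), with 3 members lower when adjusted over the list alone, and adjusted p = 0.127 with an estimated correlation. That call was also lost with quantile normalization (0.0723), normexp (median −0.03, 0.821), capped normexp (0.327), no filter (0.112), the common floor (0.118) and without both low-weight arrays (0.0506). In this list Eif2s3y and Ddx3y were above background on no female array, and Xist on no male array. For these genes neither the size nor the direction of the difference was measured, so the list's shift rests in part on signals near background. Fatty acid oxidation genes (median 0.26), clock genes (0.24) and stellate cell markers (0.32) shifted higher, each at adjusted p = 0.0174. They had adjusted p = 0.809, adjusted p = 0.413 and adjusted p = 0.417 with an estimated correlation, with slide as a block 0.0593, 0.0509 and 0.0438, and within slide 1 medians of 0.28, 0.29 and 0.53. Array weights ended the calls of fatty acid oxidation (0.166) and stellate markers (0.0831), leaving out both low-weight arrays did too (0.144 and 0.0506), and the mean of a gene's probes ended the clock call (0.0583). Fatty acid oxidation lost its call without female vehicle array 3 (0.0567), male dexamethasone array 1 (0.227), or female dexamethasone array 2 (0.066) or 3 (0.233). The clock list lost it without male dexamethasone array 3 (median 0.16, 0.0653) or female dexamethasone array 2 (0.166). The stellate list lost it without male vehicle array 1 (0.199), female vehicle array 3 (0.0567), male dexamethasone array 1 (0.155) or female dexamethasone array 2 (0.0952). No member of these 6 lists passed over all genes, and fry called none of the 7 lists (cholesterol adjusted p = 0.233).

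By the limma test 1 gene was called, Tg, whose difference was not measured, and 1033 had an unadjusted p below 0.05. Normexp and the mean of a gene's probes ended the call of Tg, and with probes above background on all 12 arrays Tg was not tested. The count was then 0 in each of the 3, with 241, 1083 and 882 genes at an unadjusted p below 0.05. It was 32 without female dexamethasone array 3, 5 without male dexamethasone array 3 and 3 without male vehicle array 1. Simulated 2-fold and 4-fold differences were recovered in 9.2% and 73.6% of cases. Differences of 2-fold or 4-fold could therefore not be ruled out, and smaller ones still less.

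The fourth question was how the sexes differ without glucocorticoid. Under vehicle Xist, which silences an X chromosome in females, was at least 2572-fold higher in females (adjusted p = 7.11e-12, n = 3 per group). The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were at least 497-fold, 173-fold and 37.1-fold lower (adjusted p = 8.88e-07, 1.1e-10 and 3.44e-08). The sulfotransferase gene Sult2a2 was higher in females by 11.91 ± 0.68 (adjusted p = 7.79e-06), and was above background on 2 of 3 male arrays. A1bg was at least 985-fold higher (adjusted p = 0.000113), and Cyp2b9 was higher by 4.70 ± 0.53 (adjusted p = 0.00103). Elovl3, a fatty acid elongase gene, was lower in females at −5.33 ± 0.39 (adjusted p = 7.01e-05), and the asparagine synthetase gene Asns at −3.43 ± 0.30 (adjusted p = 0.000205). The steroid dehydrogenase gene Hsd3b5 was lower at −4.95 ± 1.03 (adjusted p = 0.0367; within slides −1.81, −6.30 and −6.72), and 0.146 without male vehicle array 2. Within slides 1, 2 and 3 Sult2a2 differed by 11.61, 12.22 and 11.90, with slide-block adjusted p = 4.41e-07. The Xist probe lies at chromosome X, 98790940 to 98790999 in mm7.

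Among 23 female-biased liver genes tested under vehicle, 14 were higher in females, 0 lower and 9 not past, and 20 were higher when adjusted over the list alone. Their median was 3.64 (adjusted p = 1.11e-36, within slides 2.68, 3.46 and 4.57), and the call held with an estimated correlation (adjusted p = 0.00127). Of 17 male-biased genes 0 were higher, 8 lower and 9 not past, with 13 lower when adjusted over the list alone. Among them C6 was at −3.49 ± 0.32 (adjusted p = 0.000282) and Cyp4a12a at −1.97 ± 0.21 (adjusted p = 0.000816). That median was −1.09 (adjusted p = 3.87e-18, within slides −0.70, −1.33 and −1.59), and the call held with an estimated correlation (adjusted p = 0.0476). Of the Y-linked and X-inactivation genes 2 were higher and 4 lower, with 3 and 4 when adjusted over the list alone (median −2.48, adjusted p = 0.016, within slides −2.53, −2.54 and −2.37), and adjusted p = 0.141 with an estimated correlation. With only probes above background on all 12 arrays this list turned to 0.57, because its Y-linked genes then drop out, and normexp ended its call (−0.58, adjusted p = 0.155).

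Lipid and drug metabolism lists also differed between the sexes under vehicle. Cholesterol genes had 0 of 22 past the threshold and 8 higher in females when adjusted over the list alone. Their median was 0.61 (adjusted p = 1.01e-10, within slides 0.74, 0.05 and 1.10), and adjusted p = 0.261 with an estimated correlation. Xenobiotic genes had 3 higher, 0 lower and 16 not past (5 when adjusted over the list alone), among them Cyp2b10 by 2.40 ± 0.26 (adjusted p = 0.000698) and Abcb1a by 2.00 ± 0.23 (adjusted p = 0.0011). Their median was 0.33 (adjusted p = 2.83e-05, within slides 0.60, 0.06 and 0.41; 0.20 without male vehicle array 2), and adjusted p = 0.206 with an estimated correlation. Of 8 adipocyte markers on the list only 4 were tested, and their RNA levels do not count cells. Of these 4, 2 were lower in females (3 when adjusted over the list alone). They were Cidec at −2.41 ± 0.25 (adjusted p = 0.00062) and Cfd, which encodes complement factor D, at −8.58 ± 1.39 (adjusted p = 0.0101, but 0.0502 without male vehicle array 2). The median of the 4 was −1.66 (adjusted p = 8.69e-05, within slides −2.02, −1.54 and −1.42), and adjusted p = 0.13 with an estimated correlation. Without a filter on dim probes it was −0.83, and 0 with a common floor, where the list stayed called (adjusted p = 0.0054). Fatty acid synthesis (median 0.37, adjusted p = 0.0013, within slides 0.41, −0.03 and 0.69) had 1 higher, and 3 higher and 1 lower when adjusted over the list alone, and adjusted p = 0.384 with an estimated correlation. The growth hormone axis (median 0.15, adjusted p = 0.0397) had adjusted p = 0.423 with an estimated correlation, and was lost without male vehicle array 2 (0.0689), female vehicle array 1 (0.194) or female dexamethasone array 3 (0.064), and in 6 other settings besides fry (among them quantile normalization, 0.0694, and cyclic loess, 0.0915). Its 1 gene past the threshold was the prolactin receptor gene Prlr, at 2.18 ± 0.38 (adjusted p = 0.0146; 0.0779 without male vehicle array 2 and 0.0735 without male vehicle array 3).

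Several immune lists were higher in females under vehicle, mostly without single genes passing, whereas B cell markers (median 0.30, adjusted p = 0.107, within slide 1 −0.60), neutrophil markers (0.17, 0.496) and the acute phase list (−0.25, 0.119) were not called. Kupffer cell markers had 0 of 13 past and 0 when adjusted over the list alone (median 0.71, adjusted p = 1.67e-06, within slides 0.67, 1.17 and 0.30), and adjusted p = 0.322 with an estimated correlation. T and NK cell markers had 0 of 17 past, and 4 higher and 1 lower when adjusted over the list alone (median 0.66, adjusted p = 1.03e-05, within slides −0.13, 1.42 and 0.43), and adjusted p = 0.322 with an estimated correlation. Interferon genes had 2 higher and 5 when adjusted over the list alone (median 0.36, adjusted p = 2.31e-06, within slides 0.42, 0.65 and 0.30; 0.18 without male vehicle array 3), and adjusted p = 0.13 with an estimated correlation. Inflammatory genes (median 0.38, adjusted p = 0.00283, within slides 0.10, 0.78 and 0.10) had adjusted p = 0.384 with an estimated correlation and were not called without male vehicle array 3 (median 0.12, adjusted p = 0.0707). Immediate early genes (median 0.69, adjusted p = 0.0042; within slide 1 −0.13) had adjusted p = 0.422 with an estimated correlation. Endothelial markers (median 0.24, adjusted p = 0.00423) had adjusted p = 0.419 with an estimated correlation, and were lost without male vehicle array 2 (0.0689) or female vehicle array 2 (0.134). Fkbp5 (0.52 ± 0.43, adjusted p = 0.651) and Nr3c1 (0.27 ± 0.21, adjusted p = 0.623) did not pass. The glucocorticoid receptor targets were not called as a list (median −0.26, adjusted p = 0.549).

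Under vehicle 381 genes differed between the sexes in limma, 127 higher and 254 lower in females, and 311 of them by at least 2-fold. All calls kept their direction within each of the 3 slides, where over all genes 71.9%, 73.2% and 80.5% did. The same arrays made the calls, so this agreement was largely built in. All 14 list calls held with slide as a block, which gave 433 genes. Both vehicle groups were spread evenly over the slides, so the block could not change their fold changes. All 3 male vehicle arrays sat at the same slide position, so position and sex could not be told apart here. With fry the lists of cholesterol (0.0812), fatty acid synthesis (0.219), inflammatory (0.264), growth hormone (0.264) and immediate early genes (0.278) were not called, nor were markers of Kupffer cells (0.145), T and NK cells (0.145) and endothelial cells (0.257). The count was 158 without male vehicle array 2, 176 without male vehicle array 3 and 88 after normexp. The 10 splits were too few for a test by chance (the real split gave 381, the highest other 1).

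The last question was how the sexes differ under dexamethasone. Xist was at least 2254-fold higher and Sult2a2 at least 3406-fold higher in females (adjusted p = 8.46e-12 and 2.97e-06, n = 3 per group). The cytochrome gene Cyp2a4 was higher by 2.47 ± 0.24 (adjusted p = 0.000301). Eif2s3y and Ddx3y were at least 666-fold and at least 309-fold lower. Asns was lower in females at −5.01 ± 0.30 (adjusted p = 9.37e-06), Moxd1 at −6.08 ± 0.53 (adjusted p = 0.000177) and Hsd3b5 at −6.13 ± 1.03 (adjusted p = 0.00832). Cyp2b9 did not pass at 1.43 ± 0.53 (adjusted p = 0.145), but passed without male vehicle array 1 (adjusted p = 0.00134). That array is in neither group compared here, so leaving it out changed only the shared spread. Within slide 1, the only slide with both groups, Asns differed by −5.89 and Moxd1 by −6.97, and their slide-block adjusted p were 0.000479 and 0.00253.

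Of 23 female-biased genes 17 were higher in dexamethasone-treated females, 0 lower and 6 not past, and 21 were higher when adjusted over the list alone. Their median was 2.77 (adjusted p = 9.43e-24, within slide 1 2.42), and the call held with an estimated correlation (adjusted p = 0.00596). Of 17 male-biased genes 0 were higher, 14 lower and 3 not past, with 15 lower when adjusted over the list alone. Cyp7b1 was at −3.26 ± 0.30 (adjusted p = 0.000265) and Gstp1 at −1.79 ± 0.15 (adjusted p = 0.000126). Their median was −1.29 (adjusted p = 1.17e-15, within slide 1 −1.23), and adjusted p = 0.0646 with an estimated correlation. Y-linked and X-inactivation genes had 1 higher and 4 lower, with 3 and 5 when adjusted over the list alone (median −3.13, adjusted p = 0.00138, within slide 1 −3.19; 0.32 with only probes above background on all 12 arrays), and adjusted p = 0.0646 with an estimated correlation. Only 4 of 8 adipocyte markers were tested, and their RNA levels do not count cells. Of these 3 were lower, and 3 when adjusted over the list alone (median −1.52, adjusted p = 0.0031, within slide 1 −1.73), with Cidec at −1.71 ± 0.25 (adjusted p = 0.00439). The adipocyte markers had adjusted p = 0.242 with an estimated correlation, and were not called without a filter on dim probes (−0.50, 0.0799) or with the mean of a gene's probes (−0.70, 0.124). With a common floor their median was only −0.03. The marker Car3 turned to 0.713 with the mean of its probes.

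Some interferon genes were higher in dexamethasone-treated females than in males, with 9 higher, 0 lower and 16 not past, and 11 higher and 1 lower when adjusted over the list alone. Gbp3 was higher by 1.60 ± 0.19 (adjusted p = 0.00154) and Gbp2 by 1.19 ± 0.17 (adjusted p = 0.00473). Their median was 0.71 (adjusted p = 1.07e-06, within slide 1 0.65), and adjusted p = 0.105 with an estimated correlation. T and NK cell markers had 7 higher, 0 lower and 10 not past, and 10 higher when adjusted over the list alone, with Gzmb higher by 1.75 ± 0.31 (adjusted p = 0.0106, but 0.1 with slide as a block). Their median was 0.94 (adjusted p = 1.33e-06, within slide 1 0.54), and adjusted p = 0.25 with an estimated correlation. Normexp ended that call (0.09, adjusted p = 0.0549). Kupffer cell markers had 1 higher and 12 not past, but 12 higher when adjusted over the list alone (median 0.91, adjusted p = 1.07e-06, within slide 1 0.32), and adjusted p = 0.25 with an estimated correlation. Stellate cell markers (2 higher, 4 when adjusted over the list alone, median 0.47, adjusted p = 0.000706) had adjusted p = 0.151 with an estimated correlation. Endothelial markers (1 higher, median 0.45, adjusted p = 0.000365, within slide 1 0.24, and 0.17 with slide as a block), inflammatory genes (2 higher and 1 lower, 5 and 1 when adjusted over the list alone, median 0.46, adjusted p = 0.000778, within slide 1 0.71) and xenobiotic genes (6 higher, 7 when adjusted over the list alone, median 0.25, adjusted p = 0.00271, within slide 1 0.39, and 0.07 without female dexamethasone array 3) each had adjusted p = 0.25 with an estimated correlation.

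The heat shock list was called lower in dexamethasone-treated females (median −0.41, adjusted p = 0.0123), although Asns alone of its 15 members passed. It had adjusted p = 0.25 with an estimated correlation and 0.103 with slide as a block, and was lost without male dexamethasone array 3 (median −0.25, 0.0631) or female dexamethasone array 3 (0.0791). It was also lost without a filter on dim probes (0.118), with array weights (0.0505), with a capped local background (0.0897) and without both low-weight arrays (0.144). Amino acid breakdown (median 0.15), clock genes (0.35) and fatty acid synthesis (0.24) were each called at adjusted p = 0.0488, with adjusted p = 0.647, adjusted p = 0.25 and adjusted p = 0.627 with an estimated correlation. With slide as a block they had adjusted p = 0.119, 0.0792 and 0.0905, with median centring 0.0682, 0.0614 and 0.0614, with the mean of a gene's probes 0.0879, 0.115 and 0.0662, and with fry 0.367, 0.0702 and 0.347. The amino acid list lost its call in 9 of 12 fits with 1 array left out (highest adjusted p = 0.226, without female dexamethasone array 3, median 0.06), fatty acid synthesis in 9 (0.527, without male dexamethasone array 3, median 0.05) and the clock list in 7 (0.207, without female dexamethasone array 2), with a median of 0.21 without male dexamethasone array 3. Fry also did not call the inflammatory (0.0654) and endothelial (0.051) lists. The glucocorticoid receptor targets were not called (median −0.43, adjusted p = 0.0933; 0.04 with slide as a block), nor were Fkbp5 (−0.07 ± 0.43, adjusted p = 0.937) and Tat (−0.43 ± 0.26, adjusted p = 0.348).

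Under dexamethasone 1123 genes differed between the sexes in limma, 633 higher and 490 lower in females, and 612 of them by at least 2-fold. All kept their direction within slide 1, as 80.8% of all genes did, but its arrays also made the calls, so this was largely built in. With slide as a block only 244 passed, 230 of them among the 1123. Only slide 1 held both groups, so the block also leaves this comparison with less information, and the fall alone does not show an effect of slide. Of the 244, 35.7% were higher in females, against 56.4% in the main fit. The share was also below 50% without a filter on dim probes (22.5%), with normexp (44.1%) and with a capped local background (40.1%), so the balance of directions was not stable. Leaving out female dexamethasone array 1 or 2 gave 455 and 600, leaving out male dexamethasone array 1, 2 or 3 gave 593, 624 and 737, and normexp gave 59. On slide 1 the male dexamethasone array sat at a lower position than the female one, so position and sex could not be told apart there. The 10 splits were too few for a test by chance (the real split gave 1123, the highest other 11).

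The sex differences under the 2 treatments overlapped. Xist and Sult2a2 were higher in females under both, and Elovl3, Asns, C6 and Ddx3y lower under both. In total 98 genes were higher in females under both (4.2 expected for independent lists) and 170 lower (6.4 expected), with 0 in opposite directions and a correlation of 0.724 over all genes. Of 113 genes that passed under vehicle alone 95.6% had the same sign under dexamethasone, and of 855 that passed under dexamethasone alone 92.5% had the same sign under vehicle. With 1 gene past the test of the difference, the larger count under dexamethasone is not evidence that sex differences grew. With slide as a block the order of the counts was reversed, at 433 under vehicle and 244 under dexamethasone. The vehicle groups were spread evenly over the slides, but only slide 1 held both sexes under dexamethasone. The block therefore weakens the test under dexamethasone more, and the reversal does not show which sex difference is larger.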

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

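The fits with slide as a block, with 1 array left out and with an estimated correlation were set before the data were examined, but the tests that read them against the cholesterol pattern were chosen after the result was seen.

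The cholesterol synthesis and uptake genes had a lower dexamethasone effect in females than in males, with a median difference of −0.927. Part of this lies in the vehicle groups, where the list's median was 0.606 higher in females. Under dexamethasone the list was not called for a sex difference. All male vehicle arrays sat at the same slide position, so an effect of position in that group cannot be told apart. An uneven spread of the groups over the slides might explain the lower effect in females. With slide as a block the median difference was −1.059, which argues against the slides as the source of its size. The list's adjusted p = 6.1e-12 in that fit was taken at the preset correlation of 0.01. It therefore cannot decide whether the shift exceeds the spread between animals. A single array might also explain it, but the smallest median with 1 array left out was −0.723 (without female dexamethasone 2), which argues against that too. The list's genes may vary together between animals for reasons unrelated to sex, and the estimated correlation gave adjusted p = 0.28, so this stays open. A planned study with more animals per sex, measuring Mvd and Lss by quantitative PCR, would tell these apart.

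The count of 1 gene called for the difference of dexamethasone effects between the sexes could have come from chance in how animals fell into groups. Of 100 assignments of sex within each treatment, 6 called at least as many genes, the real one among them, and the highest other count was 139, so chance cannot be excluded. Why some assignments called many times the real count was not tested. Those with 139 and 34 genes both put the 2 low-weight arrays, female vehicle 2 and female dexamethasone 3, on the male side. How many genes other assignments with both arrays on that side called was not examined. The 1 gene was Tg, with a fitted difference of −3.899, whose size and direction were not measured because Tg was above background on no vehicle array.

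The median difference was 0.255 for fatty acid oxidation and PPAR alpha targets and 0.245 for the circadian clock. It was −0.236 for Y-linked and X-inactivation genes and −0.703 for immediate early genes, which was −0.30 without female vehicle 1. In the Y-linked list Eif2s3y and Ddx3y were above background on no female array and Xist on no male array, so their differences were not measured. Heat shock and unfolded protein response genes had −0.527, and stellate cell and fibroblast markers 0.318. None of these 6 lists was called with an estimated correlation (adjusted p = 0.809, 0.413, 0.127, 0.809, 0.194 and 0.417, in this order), and none with fry.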

How the results depend on the processing

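The tests with a capped local background, with a common floor and without the 2 low-weight arrays were chosen after the result was seen.

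With quantile normalization, median centring and cyclic loess the counts were 4503, 4045 and 4386 genes in males and 2775, 2190 and 2799 in females, and among named genes 366 of 378 kept their status under quantile normalization. These 3 scalings ended 4, 4 and 3 of 58 list calls. Quantile normalization took the male median of amino acid breakdown from 0.475 to 0.23 and that of gluconeogenesis from 0.524 to 0.301, and ended the male heat shock call (adjusted p = 0.132). Of the 58 list calls, 4 held with an estimated correlation and 33 with fry. The deposited series values equalled the processed signal, so a fit on them was not run. The replicate numbers do not pair animals: same-number arrays had a median residual correlation of −0.108, and 2 of 12 arrays correlated best with their own number but 8 with their own slide.

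Counts that moved by more than 1.5 times follow. In males (4359) they were 899 with normexp, 1887 at 2-fold, 1989 at adjusted p below 0.01, and 2342 without male vehicle 1. Leaving out 1 array gave at most 5026 (without female dexamethasone 3). In females (2644) they were 508 with normexp, 1180 with only the groups compared, 4036 with array weights, 1149 at 2-fold and 924 at adjusted p below 0.01, and 1504, 1742 and 1703 without female vehicle 1, female vehicle 3 and female dexamethasone 2, with at most 2568 (without male dexamethasone 3). For the difference between the sexes (1) they were 0 with normexp, with probes above background on all 12 arrays and with the mean of a gene's probes, 2278 without a filter, 3 with array weights, 2 with capped normexp, 36 without both low-weight arrays, and 3, 5 and 32 without male vehicle 1, male dexamethasone 3 and female dexamethasone 3. Under vehicle (381) they were 88 with normexp, 244 with replicate block, 224 with only the groups compared, 742 with array weights, 236 with the common floor and 151 at adjusted p below 0.01, and 158 and 176 without male vehicle 2 and 3, with at most 436 (without female dexamethasone 3). Under dexamethasone (1123) they were 59 with normexp, 4233 without a filter, 244 with slide block, 703 with replicate block, 491 with only the groups compared, 2349 with array weights, 727 with the common floor, 612 at 2-fold and 301 at adjusted p below 0.01. There they were 593, 624 and 737 without male dexamethasone 1, 2 and 3, and 455 and 600 without female dexamethasone 1 and 2, with at most 1281 (without female dexamethasone 3). For both sexes (2003) they were 379 with normexp, 1277 with slide block, 901 with only the groups compared, 827 at 2-fold, 696 at adjusted p below 0.01, and 1327 and 1196 without male vehicle 1 and female vehicle 1, with at most 1814 (without female dexamethasone 3).

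With normexp these turned in males: B cell markers 0.441 (0.212 in females), T and NK cell markers 0.396, Ranbp3l 0.365, Stap1 0.098, Akap6 0.382, Ccr7 0.562, Gzmb 0.356, Cd3g 0.315, Lck 0.099, Cd22 0.151, Fcer2a 0.617 and Cela1 0.117. In females Snai3 (0.392), Tnfaip8l3 (0.307), Rnf225 (0.399), Cd22 (0.079) and Fcer2a (0.369) turned, and under dexamethasone the sex difference of Cd22 (−0.007). With the mean of a gene's probes the sex difference of Car3 under dexamethasone turned (0.713). With probes above background on all 12 arrays the sex difference of the Y-linked list turned (0.574 under vehicle, 0.321 under dexamethasone). The side with more calls was not stable. The share of male calls that were higher was 46.3%, but 51.3% with median centring and 55.3% with capped normexp. For the sex difference under dexamethasone it was 56.4%, but 44.1% with normexp, 22.5% without a filter, 35.7% with slide block, 40.1% with capped normexp and 47.7% with the common floor. Under vehicle it was 33.3%, but 51.1% with normexp.

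Normexp might have failed because of single spots with a very bright local background. On male dexamethasone 1 and female dexamethasone 3 the brightest local background was 11368 and 20654, against at most 103 on the other arrays. The fitted mean background was −399 and −514.7 there, against −12.4 to −4.2 on the other arrays. With the local background capped 3594 genes were called in males, against 899 without the cap and 4359 without normexp, which fits that cause. The 2278 genes called without a filter for the difference between the sexes may reflect that the lowest signals differ between arrays. With a common floor 1 gene was called, the fall that this cause predicts. But a floor sets all lower signals to the same value whatever made them differ, so the fall cannot decide on the cause. Of the 2278 genes 2161 were above background on no array, so those calls rest on signals near background.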

Other observations

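The tests in this part were chosen before the result was seen, except that Cyp2b9 and its relatives were put together after the result was seen.

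The cytochrome gene Cyp2b13 was higher in females by 4.92 ± 0.39 under vehicle (adjusted p = 0.000113), Cyp2b9 by 4.70 ± 0.53 and Cyp2b10 by 2.40 ± 0.26. In males dexamethasone raised Cyp2b10 and Cyp2b9, the second by 3.69 ± 0.53, and it raised Cyp2b13 by the probe used, while 1 of the 2 probes of Cyp2b13 had the other sign. In females Cyp2b9 was at 0.42 ± 0.53, and the test of its difference between the sexes did not pass (−3.27 ± 0.75, adjusted p = 0.475), although it passed without male vehicle array 1 (−4.10, adjusted p = 0.000245). The flavin monooxygenase gene Fmo2 rose in both sexes, by 2.32 ± 0.22 in males (adjusted p = 0.00018) and by 1.44 ± 0.22 in females (adjusted p = 0.00304). Cidec, a lipid droplet gene, also rose in both, by 1.26 ± 0.25 in males (adjusted p = 0.00567) and by 1.95 ± 0.25 in females (adjusted p = 0.00119).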
